A study of Mus musculus with 4 samples.

How the data were processed

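Poly(A) RNA was measured by RNA-seq in 4 libraries, each from a pool of 5 C57BL/6 mouse blastocysts. Embryos came from superovulated females and were cultured in vitro, per the labels' protocols. The knockout group received CRISPR-Cas9 against Ywhaz as zygotes. The labels disagree on the control group, which is given as Cas9 protein alone, as a control guide RNA and as untreated, and the knockout libraries carry names that begin with si although the labels describe genome editing. All 4 libraries share one batch label, so no batch could be compared. Libraries were selected with oligo(dT) beads after Trizol extraction, per the labels' protocols.

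The deposited table holds one row per gene, with FPKM for each library, rounded to 3 decimals by the authors. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0, StringTie 1.3.1, RSEM, DESeq2 and the build GRCm39, without their roles. The group means in the deposited table are also FPKM, with 0.001 in place of 0. The deposited log2 fold change is the log2 of the knockout mean over the control mean, per the file headers and the values. The deposited p-value and FDR columns are the authors', and the tool behind them is not given in the sources used here. The table also attaches KEGG pathways to genes. Of 22013 rows, 4858 were at 0 in every library and 112 had no symbol. Every column of per-library values matched a sample's labels.

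Because the table holds FPKM and no counts, tests were made on log2(FPKM + 1). The count-based tests planned before the data were examined could not be run. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 9544 in all. limma 3.58.1 in R 4.3.3 was fitted with an intensity trend on an intercept and the group, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Means ± SD are of FPKM. Knockout minus control is the sign of every fold change.

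Before the data were examined, 30 gene lists were fixed from general knowledge, covering lineages, signalling, metabolism, stress, the cell cycle, RNA quality, embryo sex and other cell types. Of their 674 symbols, 33 were not matched in the table. The 24 lists with at least 5 tested members, and 320 KEGG pathways with 10 to 500 tested members, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists or over the pathways. After the data were seen, 2 lists were added, for nucleolar ribosome biogenesis and for heat shock proteins and co-chaperones, and tested apart from the others. Camera with an estimated correlation and fry were run as alternatives. With 2 residual degrees of freedom the estimated correlation leaves camera little power, so a call lost there is not shown to be false. Camera was planned on log2 CPM and was run on log2(FPKM + 1). Members were also adjusted over the list alone.

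Genes named in the text followed a rule set before the data were examined. It took the 14-3-3 family, a fixed set of lineage genes and Cdkn1a, and up to 10 genes each way with the largest fold change among those past the threshold. These needed a mean of at least 5 FPKM, no overlap between groups, and a symbol that is not that of a predicted gene. Where fewer than 10 genes met this, the 10 smallest p-values under the same filters were added. Up to 4 members with the smallest p were taken from each list and each named pathway, and 3 genes each way with the smallest p from the top 5% by abundance. The rule was written for CPM and was read as FPKM. Ubl5b, Ubl5c, ENSMUSG00000121570, the parent genes of copies, and the genes of the lists and families added in the closing section were chosen after their values were seen.

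Depth was estimated from the spacing of low values. In single-transcript genes longer than 1500 nt, with an assumed fragment of 200 nt, 90.7% to 94.3% of low values lay within 10% of a whole number of fragments. These estimates put the libraries within a ratio of 1.05 of each other. The tests rest on the spread between 2 pools per group. Annotation came from GENCODE M21 on GRCm38, matched by gene identifier for 99.4% of rows, with 138 unmatched. The transcript Xist was not analysed here. The table gives no coordinates, so printed positions are those of GRCm38 and not of the authors' build. The library kit's use of strand in counting is not given in the sources used here, so antisense and overlapping genes could not be told apart.

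The pipeline was tested on simulated data for the knockout and control comparison. In 20 runs over 9544 genes, 200 genes were changed in each. Of 2-fold changes 31.7% were recovered, of 4-fold changes 98.1%, and 5.02% of calls were false. A list shifted by 0.3 on the log2 scale was called in 20 of 20 runs, and 1 other list was called over all runs. Noise was drawn separately for each gene and library, without variation shared between genes. The runs therefore cannot say how often lists are called falsely in the real libraries.

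Alternatives planned in advance were a pseudocount of 0.1, no filter on low values, the replicate number as a block, each library left out in turn, an effect-size threshold, and the estimated correlation and fry. Median-of-ratios, upper-quartile, TPM and quantile scaling, a filter of 5 FPKM, no intensity trend, a test against a 1.2-fold change, a crossed block and a loess correction for transcript length and GC content were chosen after the data were seen.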

Results

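Poly(A) RNA of mouse blastocysts was sequenced to compare embryos edited in Ywhaz with control embryos. The blastocyst is the preimplantation embryo with an outer trophectoderm, an epiblast and a primitive endoderm. Ywhaz encodes 14-3-3 zeta, an adaptor protein that binds phosphorylated partners. Each group held 2 libraries, and each library came from a pool of 5 C57BL/6 blastocysts. The table gives FPKM, a length- and depth-scaled expression value, for 22013 genes and holds no counts. Spacing of the lowest values gave an estimated depth, in units of 1e6 fragments, of 18.4 in each control library and of 18.1 and 17.5 in knockout libraries 1 and 2. A 2 kb transcript at 1 FPKM then stands for 35.0 to 36.8 fragments. The libraries held 15212 to 15490 genes above 0. Nothing in the labels says that the pools of a group came from separate parents or days, so p-values measure only the spread between these pools, which may be technical.

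The targeted transcript was lower in both knockout libraries than in both control libraries, and the knockout pools differed widely. Ywhaz, on chromosome 15 from 36770770 to 36796929 on the minus strand of GRCm38, stood at 143 and 123 FPKM in control libraries 1 and 2. It stood at 32.7 FPKM in knockout library 1 and at 98.2 FPKM in knockout library 2. The group means were 133 ± 14.2 and 65.5 ± 46.3 FPKM (SD, n = 2 each), so the knockout mean was 49.2% of the control mean. The log2 fold change, here and throughout on the log2(FPKM + 1) scale, was −1.21 with a standard error of 0.39, which did not pass the threshold over all genes (limma adjusted p = 0.305). It passed when adjusted over the list alone, the 14-3-3 family of 7 genes. Leaving out knockout library 2 gave −1.99 and leaving out knockout library 1 gave −0.43. Each of these rests on 1 knockout library, so the spread between knockout pools is not measured there. Edited alleles can still be transcribed, so transcript level is an incomplete check of the editing.

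No other 14-3-3 gene passed the threshold over all genes tested. Sfn, which encodes 14-3-3 sigma, an epithelial family member, measured 262 ± 1.69 FPKM in control and 455 ± 17.7 FPKM in knockout pools (SD, n = 2 each). Its log2 fold change was 0.80 ± 0.17 (SE) and its limma adjusted p was 0.173 over all genes. Sfn and Ywhaz were the 2 family members past the threshold adjusted over the list alone. Ywhah had a log2 fold change of 0.40 and Ywhab of 0.38, both short of the threshold. Ywhae at 0.12, Ywhaq at −0.11 and Ywhag at −0.05 differed by less than their standard errors of 0.18, 0.18 and 0.22.

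**Figure D1:**
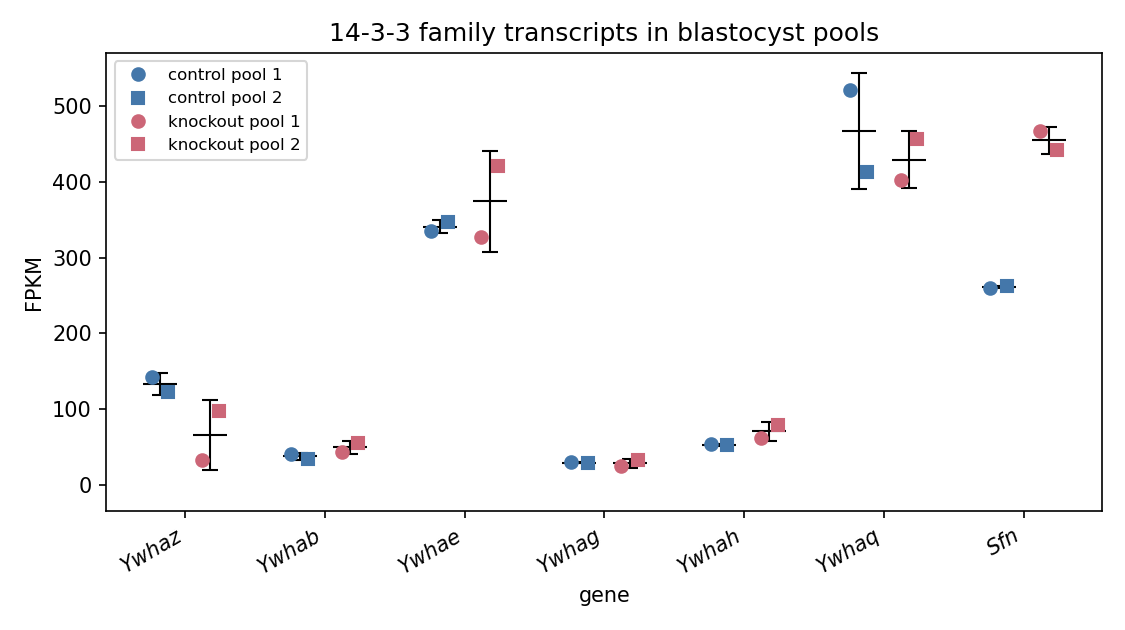
FPKM (vertical axis) of the 7 14-3-3 family genes in each library, with circles for pool 1 and squares for pool 2 of each group, and black bars for the group mean ± SD (n = 2). Ywhaz lies at 143 and 123 FPKM in control pools and at 32.7 and 98.2 FPKM in knockout pools, and Sfn lies near 262 FPKM in control and 455 FPKM in knockout pools.

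Over all 9544 genes tested, 7 passed an adjusted p of 0.05 in limma, 3 higher and 4 lower in knockout pools, against 7 higher and 6 lower with TPM scaling. Magea13, a member of the melanoma antigen family on chromosome X from 58909360 to 58920304 on the plus strand of GRCm38, fell from 86.7 ± 2.51 to 16.5 ± 5.80 FPKM (SD, n = 2 each; log2 fold change −2.37 ± 0.25 SE, limma adjusted p = 0.00726). Spp1, which encodes the secreted glycoprotein osteopontin, fell from 143 ± 32.6 to 48.9 ± 5.07 FPKM (log2 fold change −1.51 ± 0.21 SE, limma adjusted p = 0.0382). Tpsg1, which encodes a membrane-anchored tryptase, fell from 17.9 ± 2.68 to 4.34 ± 0.70 FPKM (log2 fold change −1.82 ± 0.25 SE, limma adjusted p = 0.0340). Trim43c, a member of a tripartite-motif family expressed in early embryos, rose from 7.97 ± 0.91 to 27.5 ± 2.01 FPKM (log2 fold change 1.67 ± 0.22 SE, limma adjusted p = 0.0340). Without control library 1, Spp1 and Tpsg1 lost their calls (limma adjusted p = 0.0552 for each). The Magea and Trim43 families hold similar copies, so their values are uncertain where reads could be divided between copies.

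The remaining 3 calls concerned transcripts that share sequence with other genes or carry no symbol. Rps18-ps6, an Rps18 copy on chromosome 13 from 97760072 to 97760632 on the minus strand of GRCm38, fell from 1805 ± 142 to 571 ± 97.4 FPKM (log2 fold change −1.67 ± 0.18 SE, limma adjusted p = 0.00726). Its parent gene Rps18, which encodes a small-subunit ribosomal protein, measured 6158 ± 239 FPKM in control and 7082 ± 326 FPKM in knockout pools, so the sum of both differed by −309.85 FPKM. Ubl5b, a copy of the ubiquitin-like gene Ubl5, was listed at 0 in both control libraries and at 6.55 and 4.33 FPKM in knockout libraries 1 and 2 (limma adjusted p = 0.00726). Ubl5c, another Ubl5 copy, went the other way, with 1.81 and 2.32 FPKM in control and 0.186 and 0 FPKM in knockout libraries (log2 fold change −1.49 ± 0.23 SE, limma adjusted p = 0.0767). ENSMUSG00000121570, which has no symbol in the table, was listed at 2.13 and 0 FPKM in control and at 25.4 and 33.4 FPKM in knockout libraries (limma adjusted p = 0.00726). Ubl5b, Ubl5c and ENSMUSG00000121570 were named after their values were seen, because they fall outside the naming rule.

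**Figure D2:**
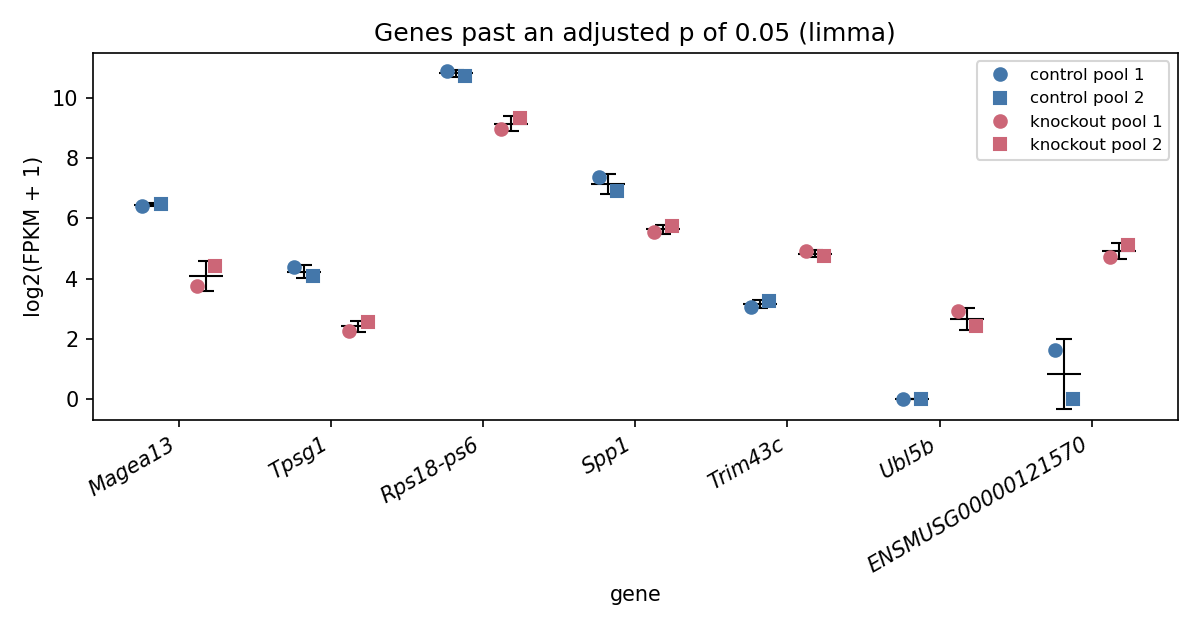
Expression as log2(FPKM + 1) (vertical axis) of the 7 genes past an adjusted p of 0.05 in limma, with circles for pool 1 and squares for pool 2 of each group, and black bars for the group mean ± SD of the log2 values (n = 2). In each of the 7 genes both knockout pools lie on one side of both control pools.

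With the 7 calls included, 1058 genes had an unadjusted limma p under 0.05, 740 with a positive and 318 with a negative log2 fold change. The count of 7 rose when any single library was left out, but such a fit leaves 1 library in a group and measures spread in the other group alone. With no filter on low values, or with quantile normalization, limma called 0 genes, with 1400 and 1249 at an unadjusted p under 0.05, and after a correction for transcript length and GC content it called 1. The median log2 fold change of all genes tested was 0.05. Knockout and control values did not overlap in 41.4% of genes, where chance gives 33.3%. Below the threshold, the naming rule took 5 more genes by smallest p, none of them past the threshold. Impdh2, which makes the guanine nucleotide precursor xanthosine monophosphate, measured 54.1 ± 0.63 FPKM in control and 127 ± 15.1 FPKM in knockout pools (limma adjusted p = 0.0755). Eif5, a translation initiation factor, measured 112 ± 2.00 and 279 ± 71.0 FPKM, and Trim43b measured 96.1 ± 3.09 and 261 ± 83.8 FPKM (limma adjusted p = 0.0767 for each). Leo1, a subunit of the PAF1 transcription elongation complex, measured 3.43 ± 0.43 and 11.5 ± 0.86 FPKM (limma adjusted p = 0.0768). Adrm1, a proteasomal ubiquitin receptor, measured 43.5 ± 6.93 and 96.9 ± 9.49 FPKM (limma adjusted p = 0.120). An exact permutation test of a single gene cannot go below p = 0.333 with 2 against 2 libraries.

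The authors' deposited table called more genes, 53 at an FDR under 0.05, of which 38 were higher and 15 lower in knockout pools. In the authors' deposited table, 47 of the 53 also had an absolute log2 fold change over 1. Of the 7 limma calls, 6 were among the 53. Of the 53, 50 were expressed highly enough to be tested in limma, all 50 had the same direction there, and 49 had an unadjusted limma p under 0.05. Hand1, a transcription factor of trophoblast giant cells, had a log2 fold change of 2.08 and an FDR of 0.0022 in the authors' deposited table. Its FPKM was 1.12 ± 0.02 in control and 4.76 ± 0.61 in knockout pools (SD, n = 2 each), with a limma adjusted p of 0.0982. Smarca4, the ATPase of BAF chromatin remodelling complexes, had a log2 fold change of 1.21 and an FDR of 0.0336 in the authors' deposited table, with 1.64 ± 0.09 and 3.80 ± 0.56 FPKM. Across tested genes, which are not independent replicates, the log2 fold changes of both sources had a Pearson correlation of 0.928 and a Spearman correlation of 0.989. Both sets of fold changes come from the same FPKM values, so shared direction and correlation are no independent support.

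Lineage lists fixed before the data were examined moved in different directions. Epiblast and pluripotency genes were higher as a list in knockout pools, with 15 of 18 tested members higher and a median log2 fold change of 0.23 (camera adjusted p = 0.0259; adjusted p = 0.936 with an estimated correlation). Pou5f1, the core pluripotency factor OCT4, measured 118 ± 4.30 FPKM in control and 190.0 ± 15.1 FPKM in knockout pools. Nanog, another core factor, measured 55.7 ± 0.09 and 81.5 ± 1.79 FPKM, and Tdh, a threonine catabolism enzyme of pluripotent cells, 1.97 ± 0.05 and 5.31 ± 0.96 FPKM. Sox2, a further core factor, measured 1.66 ± 0.48 and 1.86 ± 0.02 FPKM, and its groups overlapped. Primitive endoderm genes were lower as a list, with 14 of 19 members lower and a median of −0.20 (camera adjusted p = 0.0166; adjusted p = 0.936 with an estimated correlation). Sparc, a basement membrane glycoprotein, measured 9.66 ± 4.25 and 3.79 ± 2.29 FPKM, and Sox17, an endoderm transcription factor, 1.58 ± 0.63 and 0.522 ± 0.001 FPKM. Gata6, another endoderm factor, measured 35.8 ± 4.23 and 33.8 ± 1.63 FPKM, within the spread between pools, and Gata4, too low to be tested, 1.19 ± 0.07 and 0.497 ± 0.108 FPKM. No member of either list passed over all genes tested, and Tdh and Pou5f1 passed adjusted over the list alone. The epiblast call was lost without control library 2 (camera adjusted p = 0.121) or knockout library 2 (camera adjusted p = 0.0601), with median-of-ratios scaling (camera adjusted p = 0.0573) and at a minimum of 5 FPKM (camera adjusted p = 0.0733). The endoderm call was lost at that minimum, with a median of 0.005 (camera adjusted p = 0.565). Its median was 0.01 without control library 1 and −0.09 without knockout library 1, while the epiblast median was 0.36 without knockout library 1. The median of all genes tested was 0.12 without control library 1 and 0.13 without knockout library 1.

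Trophectoderm genes showed no common direction. Of 21 tested members 13 were higher and 8 lower, with a median log2 fold change of 0.15 (camera adjusted p = 0.669). Hand1 was the 1 member past the threshold adjusted over the list alone, and none passed over all genes. Elf5, a trophoblast stem cell factor, measured 1.69 ± 0.05 FPKM in control and 0.721 ± 0.102 FPKM in knockout pools. Krt18, a simple-epithelium keratin, measured 77.4 ± 11.3 and 119 ± 27.3 FPKM. Cdx2, which specifies trophectoderm, measured 17.0 ± 5.24 and 26.5 ± 9.28 FPKM, Gata3 22.8 ± 7.15 and 29.3 ± 9.50 FPKM, Eomes 6.21 ± 2.19 and 4.98 ± 1.75 FPKM, and Krt8 76.3 ± 5.95 and 88.9 ± 38.9 FPKM, and none of these passed. In the Hippo pathway list 13 of 18 members were higher, with a median of 0.10 (camera adjusted p = 0.528). Its kinase gene Stk4, with 4.71 ± 0.35 and 10.9 ± 1.93 FPKM, was the 1 member past the threshold adjusted over the list alone, while Tead4 had a log2 fold change of 0.34 and Yap1 of −0.03.

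Cholesterol synthesis genes were lower as a list in knockout pools, with 20 of 22 members lower and a median log2 fold change of −0.25 (camera adjusted p = 0.00232; adjusted p = 0.936 with an estimated correlation). Ebp, a sterol isomerase, measured 247 ± 70.0 FPKM in control and 149.7 ± 63.1 FPKM in knockout pools, and Dhcr7, which catalyses a last step to cholesterol, 60.3 ± 20.8 and 33.5 ± 18.6 FPKM. No member passed over all genes or adjusted over the list alone. Without knockout library 1 the median was 0.10, against 0.13 for all genes tested, so the list hardly differed from other genes there. The median was −0.04 without control library 1, against 0.12 for all genes tested. It was −0.47 without control library 2 and −0.64 without knockout library 2, against −0.004 and −0.008 for all genes tested.

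A list of replication-dependent histone genes, whose transcripts normally lack poly(A) tails, and of RNAs retained in the nucleus was fixed as a sign of RNA quality, and it was also lower. Of its 21 listed members 10 were in the table and 7 were tested, and the 4 with the smallest p were histone genes. The result therefore rests mainly on histone genes. Of the 7 tested members 6 were lower, with a median log2 fold change of −0.52 (camera adjusted p = 0.00301; adjusted p = 0.936 with an estimated correlation). H1f2, a linker histone gene, measured 12.7 ± 0.32 FPKM in control and 6.56 ± 1.63 FPKM in knockout pools and passed adjusted over the list alone. Without control library 1 the median was −0.32. H3c2 measured 4.97 ± 1.81 and 2.76 ± 0.33 FPKM. This lower level in knockout pools ran alongside the epiblast, primitive endoderm and cholesterol differences and the pathway differences given next. Mitochondrial genes held 7.83% and 9.06% of all FPKM in control libraries 1 and 2, and 9.08% and 7.57% in knockout libraries 1 and 2.

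**Figure D3:**
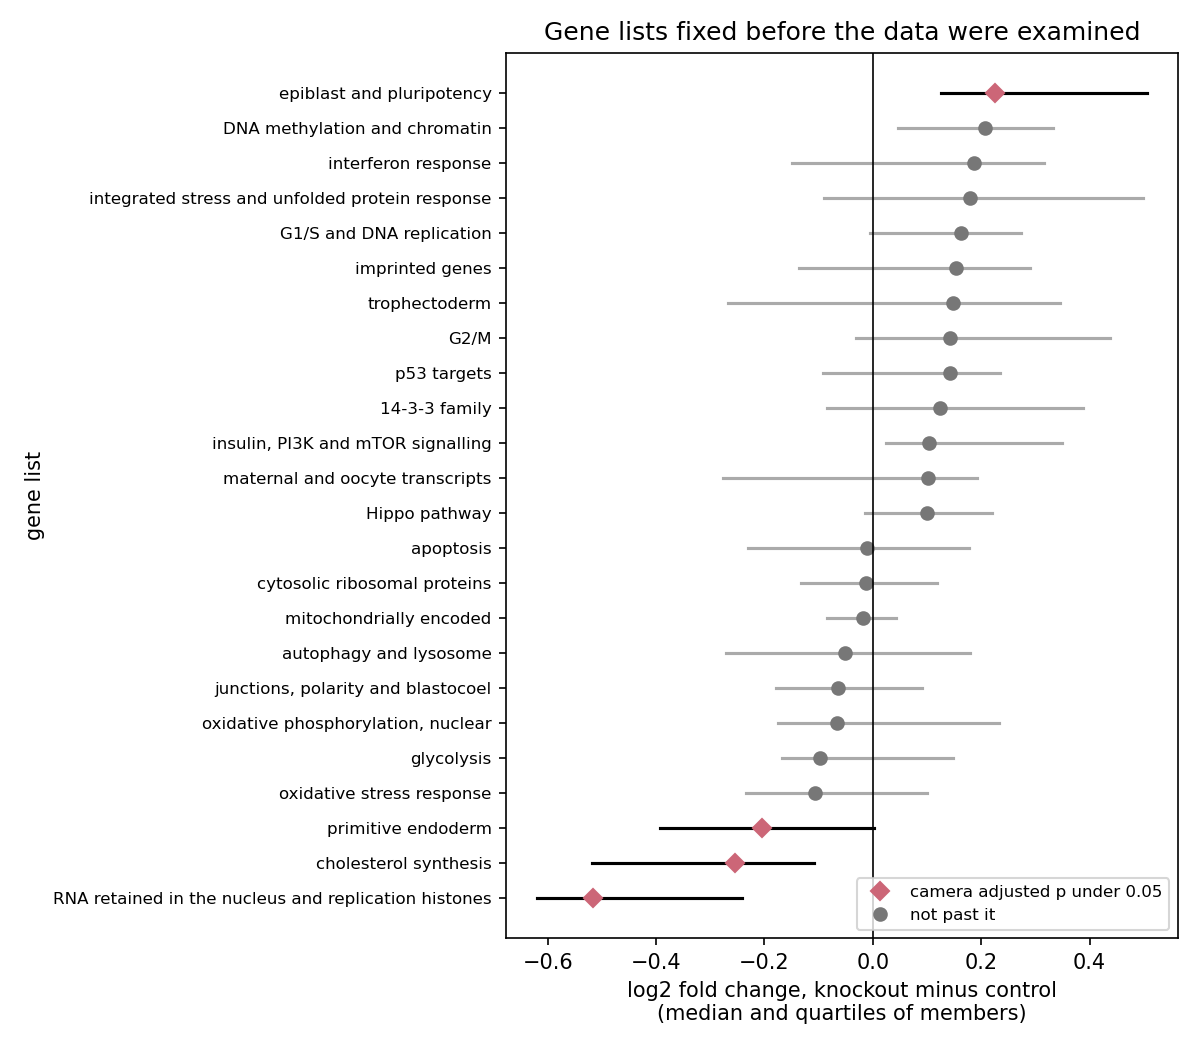
Median log2 fold change, knockout minus control (horizontal axis), of the 24 gene lists with at least 5 tested members, with lines from the lower to the upper quartile of members. Diamonds mark the 4 lists past a camera adjusted p of 0.05, at −0.52 for replication histones, −0.25 for cholesterol synthesis, −0.20 for primitive endoderm and 0.23 for epiblast genes.

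The other lists did not pass. DNA methylation and chromatin genes had 20 of 25 members higher and a median log2 fold change of 0.21 (camera adjusted p = 0.0912), and G2/M genes had 21 of 30 higher and a median of 0.14 (camera adjusted p = 0.0931). The G2/M list passed with no filter on low values (camera adjusted p = 0.0318) and with quantile normalization (camera adjusted p = 0.0254). Its median was 0.36 without control library 1 (camera adjusted p = 0.0368) or knockout library 1 (camera adjusted p = 0.0141), but 0.075 without control library 2 (camera adjusted p = 0.292) and 0.095 without knockout library 2 (camera adjusted p = 0.640). DNA methylation and chromatin genes passed without knockout library 1, with a median of 0.37 (camera adjusted p = 0.0465), and had a median of 0.082 without knockout library 2 (camera adjusted p = 0.342). Cdc20, an activator of the anaphase-promoting complex, measured 36.7 ± 3.22 FPKM in control and 60.8 ± 9.37 FPKM in knockout pools. Camera adjusted p was 0.528 for G1/S and DNA replication, apoptosis, glycolysis, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation and the integrated stress response. Without control library 1, cytosolic ribosomal proteins (median −0.17, camera adjusted p = 0.000589) and mitochondrially encoded genes (median −0.18, camera adjusted p = 0.00451) passed as lower. Mitochondrially encoded genes also passed without knockout library 1 (median −0.23, camera adjusted p = 0.00296), and glycolysis without knockout library 2 (median −0.32, camera adjusted p = 0.0181). With all libraries, camera adjusted p was 0.902 for p53 targets, and their member Cdkn1a measured 343 ± 4.18 and 366 ± 64.7 FPKM. It was 0.286 for oxidative stress, 0.371 for junctions and polarity, 0.400 for autophagy and lysosome and for insulin, PI3K and mTOR signalling, 0.547 for the 14-3-3 family, 0.669 for maternal transcripts, 0.845 for imprinted genes and 0.928 for the interferon response. Maternal transcripts had a median log2 fold change of 0.10 but a mean of −0.03 and a lower direction in camera, and nuclear oxidative phosphorylation genes a median of −0.07 but a mean of 0.001. No member of these lists passed over all genes tested.

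Lists with fewer than 5 tested members give values only. Of the 2-cell stage list 3 genes were tested, all higher: Sp110 measured 4.29 ± 0.29 FPKM in control and 10.7 ± 0.46 FPKM in knockout pools, Tmem92 4.23 ± 0.10 and 7.03 ± 1.28 FPKM, and Arg2 9.76 ± 4.36 and 13.8 ± 2.30 FPKM. Among markers of other cell types, the blood marker Hba-a1 measured 5.93 ± 0.72 and 6.95 ± 5.68 FPKM and the granulosa gene Amhr2 8.83 ± 0.83 and 7.17 ± 1.88 FPKM. Both tested members of the oviduct and uterine epithelium list had lower values in knockout pools, with a median log2 fold change of −0.58. Wfdc2 measured 32.3 ± 2.59 and 23.2 ± 8.36 FPKM (limma adjusted p = 0.510), and Muc1 12.8 ± 2.50 and 7.87 ± 2.93 FPKM (limma adjusted p = 0.433). No gene of the spermatozoa list was tested. Y-linked Eif2s3y, which follows the share of male embryos in a pool, measured 10.8 and 30.1 FPKM in control libraries 1 and 2 and 19.6 and 27.9 FPKM in knockout libraries 1 and 2.

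Among 320 KEGG pathways attached to genes in the table, 20 passed a camera adjusted p of 0.05, 7 higher and 13 lower in knockout pools. No pathway call held with an estimated correlation (smallest camera adjusted p = 0.998), and 0 of 320 had an unadjusted camera p under 0.05 there. With 2 residual degrees of freedom that test has little power, so it cannot decide whether the calls are false. Spliceosome genes were higher in 97 of 123 cases, with a median log2 fold change of 0.22 (camera adjusted p = 0.000672). Crnkl1, a splicing factor, measured 5.03 ± 0.06 FPKM in control and 11.3 ± 0.90 FPKM in knockout pools, and Snw1, another, 19.9 ± 0.68 and 35.3 ± 4.97 FPKM. Ribosome biogenesis (56 of 72 higher), mRNA surveillance (62 of 79), chromatin remodelling (75 of 99), HIV-1 life cycle, Hedgehog and FoxO pathways were higher as well. Lysosome genes were lower in 69 of 93 cases, with a median of −0.16 (camera adjusted p = 0.000672). Their members Dnase2a, which degrades DNA in lysosomes, and Ctsd, a lysosomal aspartic protease, measured 70.7 ± 8.15 against 44.3 ± 0.64 FPKM and 399.6 ± 100.3 against 252 ± 69.8 FPKM. Ctsz, taken by the same naming rule, went the other way, with 15.2 ± 0.07 FPKM in control and 28.5 ± 10.5 FPKM in knockout pools. The autophagy and lysosome list fixed in advance had a median of −0.05 and did not pass (camera adjusted p = 0.400). Steroid biosynthesis (13 of 14 lower), fatty acid elongation (17 of 22), complement and coagulation (13 of 16) and oxidative phosphorylation (84 of 124) were among the other lower pathways. With no filter on low values the lysosome (camera adjusted p = 0.0630) and steroid biosynthesis (camera adjusted p = 0.0971) calls were lost, and the latter also without control library 1 (camera adjusted p = 0.123) or knockout library 1 (camera adjusted p = 0.532). The lysosome median was −0.04 without control library 1, −0.29 without control library 2, −0.03 without knockout library 1 and −0.27 without knockout library 2. In the same settings, in that order, the median of all genes tested was 0.12, −0.004, 0.13 and −0.008. After a correction for transcript length and GC content 6 of the 20 still passed, namely spliceosome, chromatin remodelling, lysosome, steroid biosynthesis, fatty acid elongation, and complement and coagulation. Of these, the median shrank for spliceosome (0.22 before and 0.16 after) and chromatin remodelling (0.22 and 0.11), and grew in size for the rest. The correction also shifted the median of all genes tested by −0.06 (0.05 before and −0.01 after). Part of each change in a pathway median is therefore shared by all genes. Ribosome biogenesis, with a median log2 fold change of 0.19 before and 0.11 after the correction (camera adjusted p = 0.0677), and mRNA surveillance, with 0.20 before and 0.084 after (camera adjusted p = 0.113), lost their calls. The calls of the HIV-1 life cycle (camera adjusted p = 0.0677), Hedgehog (camera adjusted p = 0.139), FoxO (camera adjusted p = 0.161) and oxidative phosphorylation (camera adjusted p = 0.784) pathways were lost as well.

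On log2(FPKM + 1), the SD across genes of the difference between 2 libraries was 0.33 for the control pair, 0.41 for the knockout pair and 0.41 to 0.49 between groups. Across the same genes, which are not independent replicates, Pearson correlation was 0.990 between control libraries, 0.985 between knockout libraries and 0.978 to 0.985 between groups. The first principal component held 44.8% of the variance and parted the groups. The second held 38.1% and parted control library 2 and knockout library 1 from control library 1 and knockout library 2.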

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

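The scalings, the 5 FPKM filter, the fit without trend, the test against a fold of 1.2, the crossed block and the length and GC correction were chosen after the data were seen. The planned count-based tests (a negative binomial Wald test, voom, other count scalings, count filters) could not be run because the table holds no counts. Against 7 genes past the threshold (3 higher, 4 lower), no filter gave 0 (0 and 0), with 1400 at an unadjusted limma p under 0.05. The authors' deposited table had 1085 genes at an unadjusted p under 0.05 and 53 at an FDR under 0.05. Median-of-ratios scaling gave 4 (2 lower), upper-quartile 4 (2 lower) and TPM scaling 13 (7 higher, 6 lower). Quantile normalization gave 0 (0 and 0), with 1249 at an unadjusted limma p under 0.05. The fit with no trend gave 3 (1 lower), the length and GC correction 1 (1 higher, 0 lower) and the 1.2-fold test 4. All 7 calls stayed with an absolute log2 fold change over 1, 6 with the 5 FPKM filter and 5 with a pseudocount of 0.1. Leaving out 1 library gave 15 to 205 calls (6 to 92 higher, 7 to 126 lower), 132 without knockout library 1 and 205 without knockout library 2, with the lone sample assumed to vary like the other group. Deviations of same-numbered libraries correlated at −0.244 across genes, so the numbers were not taken to pair libraries. The replicate block gave 38 calls (21 higher, 17 lower), all 7 main calls among them, and 12 pathways, and its Ywhaz log2 fold change was −1.21 (limma adjusted p = 0.00246). The crossed replicate block gave 475 calls (323 higher, 152 lower). That block sets control 2 and knockout 1 against control 1 and knockout 2, as the second principal component did, and follows no label. Removing structure already seen in the same values favours calls, so the count is no support. Leaving out libraries moved Ywhaz between −1.99 and −0.43. The cause of these differences was not tested.

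Of lists, 4 passed, 0 with an estimated correlation, 0 with fry, 1 with the 5 FPKM filter and 3 to 7 when a library was left out. Against 20 pathways, an estimated correlation gave 0, fry 0, no filter 3, median-of-ratios scaling 12, the 5 FPKM filter 12 and the length and GC correction 6. Leaving out any single library also lost several of the 20 pathway calls. No scaling moved the median gene by more than 0.1 on the log2 scale, with the largest shift at −0.08 for median-of-ratios. With 2 pools per group, simulated 2-fold changes were recovered in 31.7% of cases, so most such changes would be missed. Of the 24 lists tested, those past the threshold kept their direction in camera under every alternative in which they were tested. The list of histone genes and nuclear RNAs was not tested with the 5 FPKM filter. Among lists short of it, the median log2 fold change in settings where camera turned direction was 0.015 for apoptosis and 0.15 for maternal transcripts with the 5 FPKM filter, 0.0069 for cytosolic ribosomal proteins, 0.10 for the interferon response and −0.036 for nuclear oxidative phosphorylation with quantile normalization, 0.072 for imprinted genes and 0.018 for the interferon response with no filter, and 0.15 for imprinted genes with the replicate block. With the length and GC correction it was 0.0015 for cytosolic ribosomal proteins, 0.13 for maternal transcripts, 0.037 for mitochondrially encoded genes and −0.036 for nuclear oxidative phosphorylation. Leaving out 1 library moved the median from −0.058 to 0.30 for the 14-3-3 family, −0.17 to 0.14 for cytosolic ribosomal proteins, 0.043 to 0.27 for G1/S and DNA replication, −0.32 to 0.21 for glycolysis, −0.087 to 0.38 for imprinted genes, 0.062 to 0.34 for the integrated stress and unfolded protein response, −0.17 to 0.38 for the interferon response, −0.23 to 0.16 for mitochondrially encoded genes, −0.0090 to 0.15 for p53 targets and −0.14 to 0.35 for trophectoderm, with camera turning direction in at least 1 case each. The cause was not tested.

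Named genes that turned direction were all short of the threshold. Their log2 fold change was −0.0068 for Cdkn1a with median-of-ratios scaling, 0.011 for Hba-a1 and 0.0017 for Yap1 with TPM scaling, 0.087 for Hba-a1 with the length and GC correction and 0.0052 for Ubl5 with quantile normalization. Leaving out 1 library moved it from −0.10 to 0.26 for Cdkn1a, −0.35 to 1.05 for Eif2s3y, −0.58 to 0.047 for Eomes, −0.19 to 0.040 for Gata6, −0.81 to 0.79 for Hba-a1, −0.31 to 0.61 for Krt8, −1.73 to 0.19 for Magea8, −0.066 to 0.30 for Sox2, −0.29 to 0.16 for Ubl5, −0.32 to 0.27 for Yap1, −0.058 to 0.30 for Ywhae, −0.25 to 0.15 for Ywhag and −0.28 to 0.054 for Ywhaq. The cause was not tested.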

Other observations

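The tests of Rps18-ps6, of gene counts in other splits, of a weaker response in knockout pool 2, of that pool's label in 3 further pairings of pools, of length and GC content as the whole cause for 3 pathways, and every test of the added lists were chosen after the result was seen. Transcripts for ribosome assembly in the nucleolus were higher in knockout pools, in a list written after the values of 5 of its members were seen. All 26 members were higher, with a median log2 fold change of 0.42 (camera adjusted p = 5.48e-09, and adjusted p = 0.0437 with an estimated correlation). The p-values of both added lists were adjusted over those 2 lists alone and rest on the data that prompted the lists. Dnttip2, a nucleolar processing factor, measured 22.4 ± 0.97 FPKM in control and 47.5 ± 0.64 FPKM in knockout pools (SD, n = 2 each), and Ncl, which encodes nucleolin, 32.6 ± 2.08 and 56.4 ± 0.02 FPKM. None passed over all genes tested in limma, and 8 passed adjusted over the list alone. The list of histone genes and nuclear RNAs fixed as a sign of RNA quality had a median of −0.52 in the same comparison, beside this list and the chaperones. Of that quality list only 7 of 21 members were tested. Without the 5 nucleolar members seen before, 21 of 21 were higher, with a median of 0.35 (camera p = 0.0448 with an estimated correlation). Leaving those members out is no independent check, since the ribosome biogenesis pathway was also higher in these same libraries. After the correction for length and GC content 22 of 26 were higher, with a median of 0.34 (camera p = 1.32e-07, but p = 0.210 with an estimated correlation). Of the 21 members not seen before, 17 were then higher and 4 lower, with a median of 0.21 (camera p = 0.000504, but p = 0.295 with an estimated correlation). In the other splits of the 4 libraries the medians were 0.01 and 0.001. This is no support, since the list was prompted by values in the real split.

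Heat shock proteins and co-chaperones, listed after the values of 3 members were seen, were higher in 19 of 23 cases, with a median log2 fold change of 0.32 (camera adjusted p = 1.86e-05, and adjusted p = 0.249 with an estimated correlation). Stip1, which links HSP70 to HSP90, measured 156.5 ± 13.3 and 307 ± 28.6 FPKM, and Hsp90aa1, the inducible HSP90, 874 ± 136.7 and 1308 ± 88.5 FPKM. Without those 3 members 16 of 20 were higher, with a median of 0.28 (camera p = 0.00303, but p = 0.444 with an estimated correlation). Splitting the libraries by replicate number gave this list a median of 0.10 (camera adjusted p = 0.0548, and under 0.05 before adjustment). Splitting control 2 and knockout 1 from the rest gave it a median of −0.13. Among multicopy families of the early embryo, Trim43a, beside the called Trim43c, measured 374 ± 26.8 and 492 ± 93.6 FPKM (limma adjusted p = 0.495), and the homeobox gene Obox6 53.2 ± 20.6 and 130.5 ± 38.6 FPKM (limma adjusted p = 0.193). Magea9 measured 1.61 and 4.91 FPKM in control libraries 1 and 2, and 0.169 and 0.038 FPKM in knockout libraries 1 and 2 (limma adjusted p = 0.129). In that family the groups overlapped for Magea8, at 27.7 and 19.4 FPKM in control and 26.5 and 6.27 FPKM in knockout libraries (limma adjusted p = 0.605), and both knockout values of Magea14 were higher, at 15.4 and 16.4 FPKM in control and 23.4 and 17.0 FPKM in knockout libraries (limma adjusted p = 0.676). These values are uncertain where reads could be divided between copies.

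Rps18-ps6 held 24.1% and 21.2% of the summed FPKM of itself and Rps18 in control libraries 1 and 2, and 6.42% and 8.53% in knockout libraries 1 and 2. The copy differed by −1234 FPKM and Rps18 by 924 FPKM in the other direction, and their sum by −309.85 FPKM. A different division of reads shared with Rps18 may therefore account for most of the lower copy, as a hypothesis. A difference in depth is argued against by a ratio of 1.05 between the deepest and the shallowest library. A change of the copy's own transcription was not tested and stays open.

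Higher RNA-processing and lower lysosomal and sterol pathways were set against transcript length and GC content, with which fold changes correlated across genes (Spearman 0.214 and −0.181). After the correction 6 of 20 pathways stayed past the threshold. Ribosome biogenesis (median 0.19 before and 0.11 after) and mRNA surveillance (0.20 and 0.084) did not, so a length and GC bias between libraries may account for part of the pattern. Among lost calls the median grew in size for drug metabolism (−0.177 and −0.196), fat digestion (−0.157 and −0.162), glycerolipid metabolism (−0.146 and −0.164) and mineral absorption (−0.120 and −0.175). It shrank for the other lost calls. The correction shifted the median of all genes tested by −0.06 (0.05 before and −0.01 after). Growth or shrinkage of these medians is therefore not growth or shrinkage against other genes. Spliceosome, lysosome and steroid biosynthesis stayed, with medians of 0.16, −0.22 and −0.41 and a largest camera adjusted p of 0.00434, so the correction did not remove their shift. These 3 were set apart after the result was seen, so they are no separate test of that bias. Of the 3 splits of the 4 libraries 2 gave as many pathways, 20 for the real one and 24 for control 2 and knockout 1 against control 1 and knockout 2, and 3 splits are too few for a share under 0.05. An effect of Ywhaz editing stays open beside that structure of the libraries.

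Gene counts had the same limit, with 2 of the 3 splits giving as many genes past the threshold, 7 for the real one and 9 for replicate 2 of each group against replicate 1. At an unadjusted p under 0.05 the real split had 1058 genes, replicate 2 against replicate 1 had 133, and control 2 and knockout 1 against control 1 and knockout 2 had 705, with 0 past the threshold. Of the fixed lists 4 passed in the real split, and 5 and 6 in those other splits, in that order.

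Ywhaz stood at 98.2 FPKM in knockout pool 2 and at 32.7 FPKM in knockout pool 1. A mislabelled control pool was tested by choosing the 200 genes that differed most in 1 pair of pools. Their direction was read in the other pair, where a wrong label would give about 50% if the pools shared no other structure. The test written before its result, chosen between knockout 1 and control 1, gave 50% (exact 95% interval 42.9% to 57.1%). The other 3 pairings gave 76% (69.5% to 81.7%; knockout 2 and control 2), 82.0% (76.0% to 87.1%; knockout 1 and control 2) and 83.5% (77.6% to 88.4%; knockout 2 and control 1). The pairings reuse the same 4 libraries, and the intervals treat genes as independent. The second principal component also grouped control 2 with knockout 1 and control 1 with knockout 2. The test therefore cannot decide whether the label is wrong, and a wrong label stays open. A weaker response throughout pool 2 stays open, since the authors' calls, of which 42% (21 of 50) lay nearer to the control mean there, were chosen from both pools. A mixture of edited and unedited cells or embryos in pool 2 was not tested and stays open.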
